A study of Homo sapiens with 31 samples.

How the data were processed

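Messenger RNA was sequenced from MCF10A cells, a non-transformed human breast epithelial line, that had been starved of serum and growth factors for 2 to 3 days and released into full medium. The medium held either 0.1% DMSO, the vehicle, or 1 µM palbociclib, an inhibitor of the cyclin D-dependent kinases CDK4 and CDK6. There were 31 libraries in 11 groups: the starved start at 0 h, DMSO at 3, 6, 9, 12, 15 and 24 h, and palbociclib at 9, 12, 15 and 24 h. Each group had 3 libraries except both 24 h groups, which had 2 (replicates 1 and 3). Groups and replicate numbers were taken from the labels. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

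Per the labels' protocols, libraries were made with a stranded poly(A) mRNA kit and read as single ends of 75 nt. Per the submitters' processing notes, FastQC 0.11.3, TopHat2 2.1.1 with Bowtie2 2.2.9, Subread 1.5.1 and the GRCh38.p7 genome were used. Per the file headers, the deposited values are raw read counts per gene name from featureCounts 1.5.1 on GENCODE 25 exons, with no strand option set and without multi-mapping or ambiguous reads. Because reads were not assigned by strand, genes that overlap another gene on the opposite strand are uncertain, and genes with near-identical copies lose reads. For the named genes, the percentage of exonic bases shared with another annotated gene was computed from the positions in the files. Counting by gene name merges loci that share a name, and 178 names had exons on more than 1 chromosome. The deposited series table held the same counts as the per-library tables in all 31 columns, but 28 of its gene names had been turned into dates, so the per-library tables were used.

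Library totals ran from 10342358 to 20878364 counts, and mitochondrial transcripts took 2.48% to 4.378% of them. Replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of 3.3 to 17.8, so each library was counted as 1 sample, though separate preparations of the same RNA would also exceed sampling noise. Of 56269 gene names, 34335 had a count in some library, and 15787 passed edgeR's filterByExpr by group and were tested. At this depth the common biological coefficient of variation was 6.55%. Counting intervals for ratios against groups with few counts cover counting error only.

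Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors (0.927 to 1.081), 1 quasi-likelihood fit of all 31 libraries by group with 20 residual degrees of freedom, and a test per contrast with Benjamini-Hochberg adjustment over the 15787 genes. A gene was called at an adjusted p below 0.05, and calls with an absolute log2 fold change of at least 1 were counted again. Adjusted p-values of genes are from this test, and a standard error (SE) is the absolute log2 fold change over the square root of F. Levels are CPM values (counts scaled by the library total) with TMM factors, given as mean ± SD over 3 libraries, or over 2 at 24 h. The 16 planned contrasts compared palbociclib with DMSO at each time, each released group with 0 h, and the palbociclib effect between 9 and 15 h and between 15 and 24 h as interactions.

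Before the data were examined, 21 gene lists were fixed. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the 21 lists, and again with an estimated correlation and with fry. A list's level in a library is its members' mean log2 CPM, compared between palbociclib and DMSO with an exact two-sided permutation test, for which 3 against 3 libraries allow no p below 0.1. Some genes are in more than 1 list: E2F1, E2F2, CDK2, RBL1 and CDC25A are in both the E2F and the CDK regulator list, FOSL1 in the immediate early and ERK output lists, SESN1 in the FoxO and p53 lists, BTG2 in the immediate early and p53 lists, CYR61 and CTGF in the immediate early and YAP lists, CCND1 in the CDK and ERK lists, CDKN1A in the CDK and p53 lists, CDKN1B and RBL2 in the CDK and FoxO lists, and SESN2 in the ATF4 and p53 lists.

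Named genes followed a rule fixed in advance. CCND1, CCNE1, CCNE2, CCNA2, CCNB1, CDKN1A, CDKN1B, RB1, E2F1, MYC, MCM2, CDC6, FOS and EGR1 could be named in any contrast. The rule added the 6 largest rises and falls in each palbociclib contrast and the 4 largest each way in each DMSO contrast and interaction, among called genes with a mean log2 CPM of at least 1, a gene symbol and, except in interactions, no overlap between the groups' libraries. It also added up to 4 members per list and direction by smallest p. Mitochondrial, Y-linked and X-inactivation genes and clone or locus identifiers were not named, and some genes that the rule selected are not reported here.

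The edgeR step was tested on simulated counts drawn from the real means and library sizes, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. The changed genes were taken only from those with an average log2 CPM over 1. Recovery of changes in genes with fewer counts was not tested. For palbociclib against DMSO at 15 h, over 15550 genes, 83.6% of the 1.5-fold, 89.6% of the 2-fold and 100% of the 4-fold changes were recovered, and 5.70% of the calls were false. At 24 h, over 15552 genes, these were 80.6%, 91.0%, 100% and 4.74%. The list test found a planted list and called 0 of 20 random lists. Simulated genes were drawn independently of each other, whereas genes of the real libraries vary together. False calls of genes or lists from such shared variation were therefore not tested.

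Alternatives fixed in advance were RLE factors, library totals, no filter and a stricter filter (CPM of 1 in 3 libraries), replicate number as a block, a fit of the contrast's own libraries, DESeq2 1.42.0, a prior count of 0.5, the other list tests, and leaving out each library. Chosen after the data were seen were a library covariate, leaving out the replicate 3 libraries of DMSO 24 h and of each palbociclib group, removal of trends over GC content or exon length, the covariate and trends taken from all genes outside the E2F G1/S, G2/M and CDK regulator lists, TMM factors without the cell cycle lists, 3 further contrasts and 5 further gene lists. GC content came from GENCODE 29 transcripts matched by name for 87.6% of the genes tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.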

Results

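Poly(A) RNA was measured in MCF10A cells, a human breast epithelial line that is not transformed and stops dividing without growth factors. Cells were starved for 2 to 3 days and then released into full medium with DMSO or with 1 µM palbociclib, a drug that blocks CDK4 and CDK6, the kinases that act with D cyclins on the retinoblastoma protein. The design asks which transcripts change as cells leave quiescence and which of these changes need CDK4/6 activity. The 31 libraries covered 0 h, DMSO at 3, 6, 9, 12, 15 and 24 h and palbociclib at 9, 12, 15 and 24 h, with 3 libraries per group and 2 at 24 h. They held 10342358 to 20878364 gene counts each. The first principal component of all libraries held 47.2% of the variance. Within groups, a main axis of variation held 27.5% of the remaining variance, on which replicate 2 of 0 h and of DMSO at 3 to 15 h scored 12.01 to 24.8 and replicate 3 of these groups −18.5 to −7.51. Loadings on this axis went with exon length (Spearman rho −0.182 over all tested genes and −0.589 over the 9520 with a mean log2 CPM over 3, genes not being independent), and 17 of 19 mitochondrial genes loaded positively. Replicate 3 of DMSO 24 h and of each palbociclib group had the opposite sign (7.84 to 27.2), and counts of calls without those 5 libraries are given beside the drug comparisons. Replicate 1 of palbociclib at 15 and 24 h had the lowest scores of all 31 libraries (−31.6 and −25.4) and stayed in those fits. Scores are deviations within a group, so the 2 libraries of each 24 h group mirror each other (−25.4 and 25.4, and −11.35 and 11.35). The axis therefore cannot tell which of the 2 stands apart at 24 h.

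**Figure D1:**
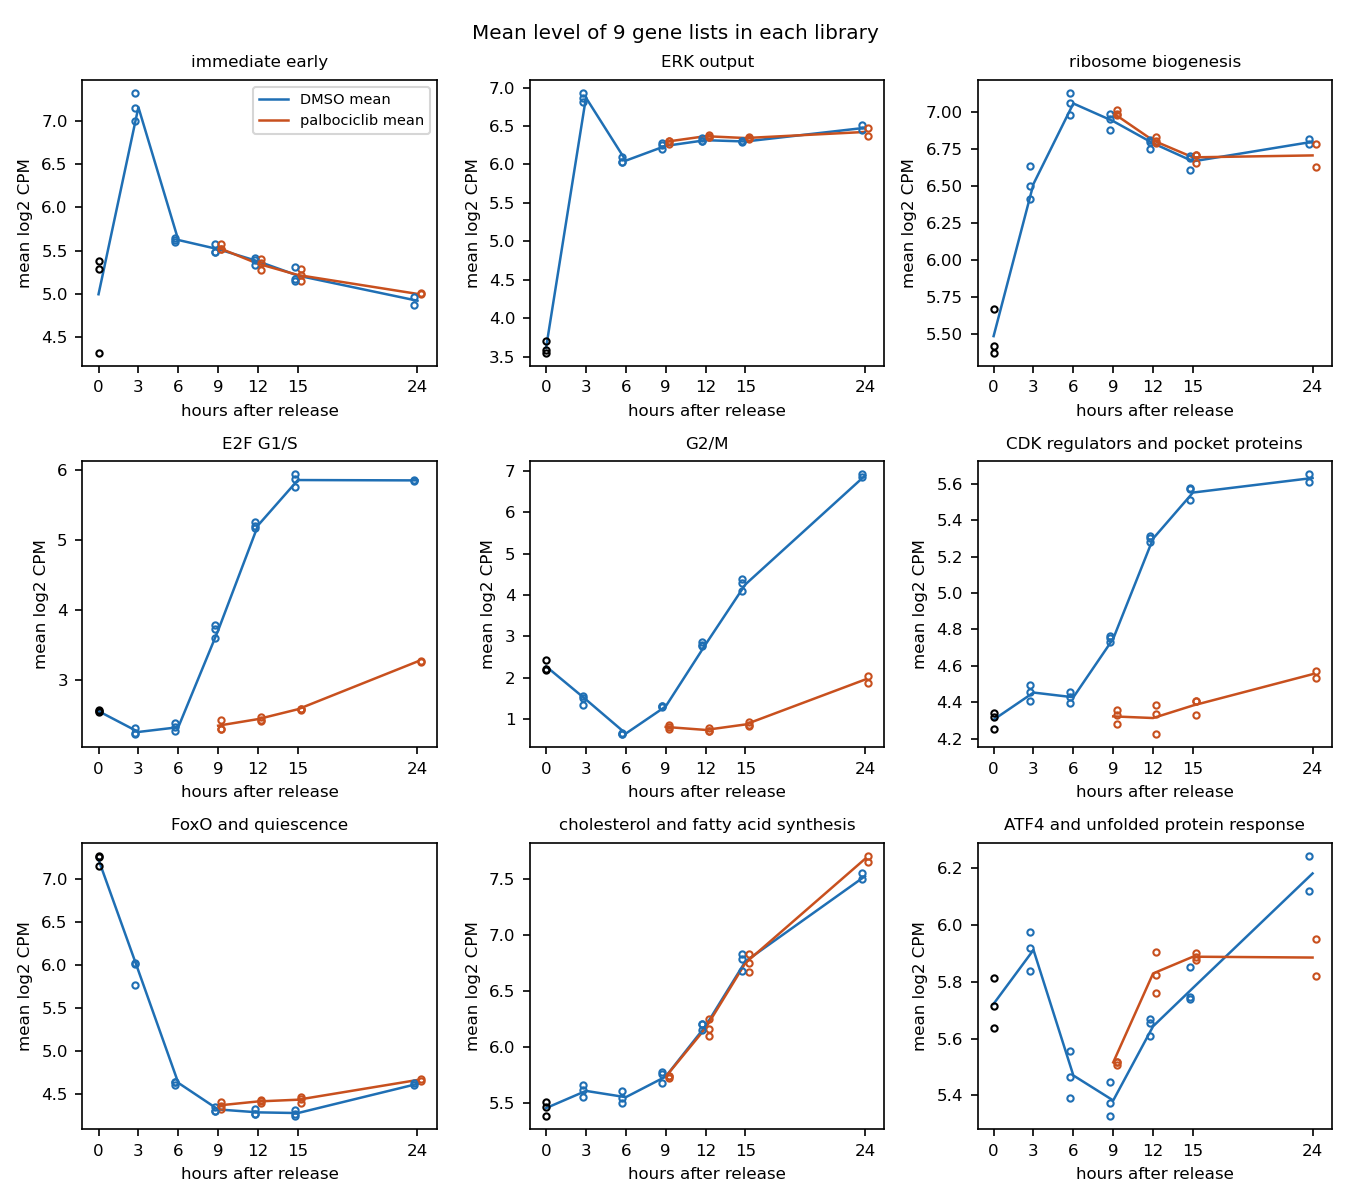
Mean log2 CPM of the members of 9 gene lists in each library (points, black for the starved cells at 0 h) and group means (lines) against hours after release, for DMSO (blue) and palbociclib (orange), each list on its own axis range. The E2F G1/S list reached 5.86 at 15 h with DMSO and stood at 2.58 with palbociclib, and the G2/M list reached 6.88 at 24 h with DMSO and 1.96 with palbociclib.

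Growth factor signalling genes had changed by 3 h after release with DMSO, the earliest time measured. At 3 h, all 18 tested members of the ERK output list, mostly feedback regulators and EGFR ligands, were higher than at 0 h, with a median log2 change of 3.42. SPRY4, an inhibitor of receptor tyrosine kinase signalling, rose by 6.87 ± 0.12 (SE) from 3.10 ± 1.1 to 360 ± 37 CPM, and FOSL1, an AP-1 subunit, rose by 5.38 ± 0.09. Of 22 immediate early genes 18 rose and 2 fell (median 1.71). FOSB rose by 6.06 ± 0.19 and SRF by 2.90 ± 0.07, whereas FOS was lower at 3 h, at 60.9 ± 4.3 CPM against 132 ± 49, by −1.12 ± 0.14. EGR1 stood at 143, 8.07 and 131 CPM in the 3 libraries at 0 h and did not pass the test at 3 h (log2 −0.57 ± 0.39). Among YAP and TGF-β targets 12 of 16 rose and 3 fell (median 2.12), including F3, the gene of tissue factor, at 6.87 ± 0.08. GJB2, the gene of connexin 26, was among the largest rises of genes with a mean log2 CPM of at least 1 (8.16 ± 0.13, from 1.85 ± 0.76 to 539 ± 20 CPM). SCNN1G, VAV3 and FBXO32 were among the largest falls of such genes, SCNN1G from 160 ± 2.9 to 5.35 ± 0.60 CPM.

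Growth and quiescence genes moved at the same time. Of 40 ribosome biogenesis genes 37 were higher at 3 h (median 1.03) and 39 at 6 h (median 1.48), and MYC rose from 320 ± 85 to 785 ± 51 CPM at 3 h. NF-κB cytokines had 11 of 15 members higher and 4 lower at 3 h (median 1.51), including CSF3 at 5.28 ± 0.20 against BIRC3 at −1.77 ± 0.10. Basal epithelial markers had 9 of 12 higher and 3 lower (median 0.67), including the laminin subunit gene LAMB3 (2.71 ± 0.05), while TP63 fell by 1.03 ± 0.10. Glycolysis and hypoxia genes had 11 of 16 higher and 3 lower (median 0.47). Of 26 FoxO and quiescence genes 23 fell and 2 rose at 3 h (median −0.96), and all 26 fell at 6 h (median −2.33). PDK4, the kinase that holds pyruvate out of the citric acid cycle, dropped from 707 ± 55 CPM at 0 h to 4.92 ± 1.3 at 6 h. CDKN1B, the gene of the CDK inhibitor p27, fell from 64.5 ± 1.6 to 16.5 ± 2.2 CPM at 3 h, and CDKN1A, the gene of p21, rose from 280 ± 31 to 869 ± 67 at 3 h and stood at 187 ± 6.5 at 6 h. CCND1, the gene of cyclin D1, rose from 57.7 ± 9.3 CPM to 209 ± 48 at 3 h and 637 ± 19 at 9 h (log2 3.46 ± 0.11; chromosome 11, 69641087 to 69654474 in GRCh38, with 10.3% of its exonic bases shared with a gene on the opposite strand). At 6 h, p53 targets fell in 19 of 26 members and rose in 3, interferon and antigen presentation genes fell in 22 of 28 and rose in 2, lysosomal genes fell in 15 of 20 and rose in 1, and polyadenylated histone transcripts fell in 12 of 14.

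In total 4393 genes were higher and 5433 lower at 3 h, of which 1681 and 1487 by at least 2-fold. At 6 h these were 5375 and 6230, of which 2178 and 2916 by at least 2-fold. Scaled counts show shares of the mRNA sequenced, not amounts per cell, so rises and falls are relative to other transcripts. Camera called the 3 h lists of ERK output (adjusted p = 1.1e-16; 3.7e-05 with an estimated correlation), YAP and TGF-β targets (2.4e-06; 0.0083) and FoxO genes (1.2e-07; 0.0083). With an estimated correlation the other 3 h calls were lost: immediate early (adjusted p = 5.6e-08, and 0.18 with an estimated correlation), ribosome biogenesis (2e-14, and 0.18), NF-κB cytokines (0.0028, and 0.31), glycolysis (0.003, and 0.31) and basal markers (0.0043, and 0.18). At 6 h the p53 list was called with both correlations (adjusted p = 4.2e-04; 0.036 with an estimated correlation), as was the FoxO list (3.5e-13; 5e-04). The 6 h calls of ribosome biogenesis (4.8e-16), glycolysis (0.001), YAP and TGF-β targets (0.047), interferon (0.004), lysosome (0.0054) and polyadenylated histones (0.0096) were lost with that correlation (adjusted p = 0.16, 0.27, 0.27, 0.34, 0.47 and 0.27). Against 0 h, scaling by library totals moved the median of all genes to −0.259 from −0.103 at 3 h and to −0.196 from −0.095 at 24 h, and turned the sign of no called list.

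The E2F G1/S list, 64 genes of cyclin E, replication licensing, replication forks and nucleotide synthesis, followed from 9 h. It had 49 members higher and 8 lower at 9 h (median 1.05), 63 higher at 12 h (median 2.27), and all 64 higher at 15 h (median 2.90) and at 24 h (median 2.92). E2F1 rose from 0.999 ± 0.22 CPM at 0 h to 9.10 ± 0.89 at 9 h and 41.9 ± 4.9 at 15 h. CDC6, a replication licensing factor, rose from 2.39 ± 0.39 to 106 ± 5.3 CPM at 15 h, and MCM2, a subunit of the replicative helicase, from 15.97 ± 1.7 to 141 ± 16. CCNE1 rose first at 3 h (1.37 ± 0.17), did not pass the test at 6 h (0.17 ± 0.20) and reached 21.3 ± 1.3 CPM at 15 h. CLSPN, with 9 counts over the 3 libraries at 0 h, rose by 8.73 ± 0.19 at 15 h. Camera called the list at 9 h (adjusted p = 1.3e-06; adjusted p = 0.096 with an estimated correlation) and, with both correlations, at 12, 15 and 24 h (adjusted p = 0.0021 at 12 h and 5.6e-04 at 24 h with the estimated correlation).

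G2/M genes followed the G1/S genes in time. Of 50 tested, 42 were lower at 3 h and 1 higher (median −0.95), 43 lower and 3 higher at 6 h (median −1.83), and 31 lower and 9 higher at 9 h (median −1.035). They were then higher in 29 and lower in 9 at 12 h (median 0.60), higher in 47 at 15 h (median 1.97) and higher in all 50 at 24 h (median 4.78). CCNB1, the gene of cyclin B1, rose from 9.04 ± 1.1 CPM at 0 h to 23.1 ± 1.5 at 15 h and 241 ± 16 at 24 h, and CCNA2 from 7.03 ± 0.92 to 178 ± 6.3 at 24 h. PTTG1, the gene of securin, was the member lower at 15 h (−1.21 ± 0.12). Camera called the falls at 3 h (adjusted p = 1.3e-04; adjusted p = 0.13 with an estimated correlation), 6 h (5.6e-07; 0.036) and 9 h (0.0127; 0.259), and the rises at 12 h (0.025; 0.32), 15 h (0.0084 with an estimated correlation) and 24 h (4.1e-04).

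Sterol and fatty acid synthesis genes went both ways at first and were all higher at 24 h. Of 27 tested, 9 were higher and 11 lower at 3 h (median −0.04), 12 and 11 at 6 h (median −0.03) and 14 and 8 at 9 h (median 0.26), none of them called by camera (adjusted p = 0.81, 0.84 and 0.25). There were 19 higher and 6 lower at 12 h (median 0.75), 21 and 3 at 15 h (median 1.60), and all 27 higher at 24 h (median 1.92). By first change of at least 2-fold, 5, 2, 1, 3, 4 and 4 members rose at 3, 6, 9, 12, 15 and 24 h, and 2 and 1 fell at 3 and 6 h. SCD, the stearoyl-CoA desaturase, rose by 4.66 ± 0.10 and FADS2 by 4.26 ± 0.10 at 24 h. CDK regulators had 21 of 25 higher and 4 lower at 24 h (median 1.13), with CDKN1C (−2.73 ± 0.16) and RBL2 (−1.19 ± 0.07) among the falls (18.2% of the exonic bases of RBL2 are shared with genes on the opposite strand). The cholesterol list was called at 12 h (adjusted p = 0.0045; adjusted p = 0.40 with an estimated correlation), 15 h (0.15 with the estimated correlation) and 24 h (3.1e-12; 0.041), and the CDK regulators at 24 h (5.5e-04; 0.038). Among the largest rises of such genes at 15 and 24 h (mean log2 CPM of at least 1), KANK4 had 1 count over the 3 libraries at 0 h and 2367 at 15 h, a ratio of 2593 with a counting interval of 465 to 102460. TFPI2, the gene of a protease inhibitor, had 1 count at 0 h and 1081 in the 2 libraries at 24 h, a ratio of 1602 (287 to 63328). ADH1B fell from 116 ± 8.7 to 0.297 ± 0.028 CPM at 24 h and ACSS1 from 96.4 ± 7.7 to 0.20 ± 0.21.

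Calls against 0 h numbered 5568 higher and 6292 lower at 9 h, 5699 and 6246 at 12 h, 5911 and 6203 at 15 h, and 5800 and 6145 at 24 h. By first change of at least 2-fold past the test, in either direction, 1681 genes rose and 1487 fell at 3 h, 992 and 1853 at 6 h, 434 and 680 at 9 h, 309 and 276 at 12 h, 216 and 200 at 15 h, and 272 and 401 at 24 h. For E2F G1/S members this first change was a rise in 3 at 3 h, 7 at 6 h, 21 at 9 h, 13 at 12 h and 5 at 15 h, and a fall in 10 at 3 h and 5 at 6 h. At 24 h the markers of other lineages split: luminal markers had 4 of 7 higher and 2 lower (KRT18 0.98 ± 0.06, MUC1 −2.73 ± 0.11), mesenchymal markers 6 of 12 higher and 5 lower (FN1 2.42 ± 0.07, DCN −3.76 ± 0.13), and squamous markers 3 of 13 higher and 7 lower (SPRR2D 2.83 ± 0.20, KRT10 −2.03 ± 0.07). None of these 3 lists, nor the 2 tested blood and endothelial markers, was called by camera at 24 h (adjusted p = 0.65, 0.94, 0.22 and 0.12). KRT18 and MUC1 share 16.3% and 11.8% of their exonic bases with other genes. At 24 h all 26 FoxO genes were lower (median −2.25) and 17 of 18 ERK output genes higher (median 2.64), both called with an estimated correlation (adjusted p = 5.3e-04 and 5.6e-04). The 24 h calls of ribosome biogenesis (39 of 40 higher), glycolysis (12 of 16 higher, 3 lower), p53 targets (5 of 26 higher, 17 lower), interferon (2 of 28 higher, 21 lower) and polyadenylated histones (12 of 14 lower) were lost with it (adjusted p = 0.175, 0.242, 0.106, 0.186 and 0.073). The mesenchymal list had a positive median (0.71) and a negative mean (−0.04). The ATF4 and unfolded protein response list was not called at 24 h (12 of 21 higher, 6 lower, adjusted p = 0.19).

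Palbociclib was compared with DMSO at each shared time to ask which transcripts differ when CDK4/6 is inhibited. Of 64 E2F G1/S genes 54 were lower than with DMSO at 9 h, 60 when adjusted over the list alone, with a median log2 change of −1.03. FAM111B, a protease gene, had 4 counts over the 3 palbociclib libraries against 994 over the DMSO libraries (log2 −7.82 ± 0.27; chromosome 11, 59107185 to 59127410). E2F1 stood at 0.452 ± 0.092 against 9.10 ± 0.89 CPM, CDC6 at 0.760 ± 0.071 against 14.7 ± 2.1, and CDT1, another licensing factor, fell by 4.04 ± 0.17. CCNE1 fell by 1.29 ± 0.18 and MCM2 by 1.68 ± 0.10, while CCND1 (0.05 ± 0.10), MYC (0.10 ± 0.10), CDKN1A (−0.12 ± 0.08) and CDKN1B (0.05 ± 0.10) did not pass the test. CCNE2 fell by 3.09 ± 0.25, though 37.1% of its exonic bases overlap genes on the opposite strand. G2/M genes were lower in 8 of 50, 22 adjusted over the list alone (median −0.47), and CDK regulators in 7 of 25, among them E2F1, RBL1 and CDC25A. Rises included NUPR1 (0.59 ± 0.15), SRSF5 (0.48 ± 0.07, 166 ± 7.8 against 119 ± 7.5 CPM) and SRSF6 (0.33 ± 0.05), which encode splicing factors, and TTC14 (0.34 ± 0.07). The NUPR1 call was lost without DMSO replicate 1 (0.54) or 3 (0.56), without any of the 3 palbociclib libraries (0.57 to 0.61), without the 5 libraries (0.59) and with exon length trends removed (0.59).

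At 9 h 18 genes were higher and 170 lower, of which 1 and 78 by at least 2-fold. The 1 gene, WDR78 (1.25 ± 0.25), was named after its values were seen. Camera called the E2F (adjusted p = 8.1e-147; 1.4e-09 with an estimated correlation), G2/M (1.8e-20; 1.9e-04) and CDK regulator lists (2.6e-08; 0.0012). It called the ATF4 list higher (median 0.09, adjusted p = 0.0025; adjusted p = 0.56 with an estimated correlation), with 1 of 21 members past the test, 3 when adjusted over the list alone. That member, HERPUD1 (0.33 ± 0.08), lost its call without DMSO replicate 1 (0.27) or 3 (0.32) or palbociclib replicate 2 (0.32) or 3 (0.25). The 18 higher genes became 6 without the 5 libraries, 9 without DMSO replicate 1, 11 without DMSO replicate 3, 10 without palbociclib replicate 2 or 3, 29 without palbociclib replicate 1, 36 with the library axis covariate, and 11 in a fit of the contrast's own libraries or with exon length trends removed, and the 170 lower genes became 275 without a filter. The drug effect at 9 h correlated across genes with the loading on the within-group axis (Spearman rho 0.322 over genes, which are not independent).

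At 12 h all 64 E2F G1/S genes were lower with palbociclib, with a median of −2.32. FAM111B stood at 0.120 ± 0.11 against 81.4 ± 3.4 CPM, MYBL2, the gene of B-Myb, at 0.221 ± 0.14 against 30.0 ± 2.4, and DTL at 2.95 ± 0.28 against 136 ± 5.4. EXO1 fell by 6.61 ± 0.20 and CLSPN by 5.48 ± 0.15. G2/M genes were lower in 46 of 50, 48 adjusted over the list alone (median −2.29), with BUB1B at −3.06 ± 0.15 (10.2% of its exonic bases are shared with a gene on the same strand) and ANLN at −2.29 ± 0.11. CCNA2 fell by 2.68 ± 0.18, and CDK regulators were lower in 11 of 25 (median −0.22). FoxO and quiescence genes were higher in 4 of 26 and lower in 1, 6 and 1 adjusted over the list alone (median 0.12). CCNG2, the gene of cyclin G2, rose by 0.49 ± 0.07 (130 ± 2.8 against 92.5 ± 2.8 CPM) and MXD4, a MAX partner opposed to MYC, by 0.49 ± 0.06, while INSR fell by 0.47 ± 0.11. Of 21 ATF4 genes 2 rose, 5 adjusted over the list alone, led by the cystine transporter gene SLC7A11 (0.54 ± 0.11).

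At 12 h 131 genes were higher and 759 lower, of which 3 and 285 by at least 2-fold. The 3 were PECAM1, ADM2 and a clone locus, named after their values were seen. The E2F, G2/M and CDK regulator lists were called with both correlations (estimated: adjusted p = 1.3e-10, 3.3e-09 and 8.8e-05). The FoxO call (adjusted p = 8.2e-04) and the ATF4 call (1.1e-04) were lost with an estimated correlation (adjusted p = 0.088 and adjusted p = 0.22). The count of higher genes moved to 59 without a filter, 239 in a fit of the contrast's own libraries, 266 with the library axis covariate, 57 without the 5 libraries, 85 with GC trends and 75 with exon length trends removed. It was 54, 60 and 74 without DMSO replicate 1, 2 and 3, and 74 and 75 without palbociclib replicate 2 and 3.

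At 15 h all 64 E2F G1/S genes were again lower (median −2.89), including RRM2, a ribonucleotide reductase subunit gene, at 2.76 ± 0.74 against 263 ± 24 CPM and TK1, the thymidine kinase, at 0.394 ± 0.15 against 38.4 ± 7.3. FAM111B was at 0.151 ± 0.080 against 146 ± 12 CPM. G2/M genes were lower in 49 of 50, all 50 adjusted over the list alone (median −3.81), and MKI67, the gene of the proliferation marker Ki-67, stood at 1.91 ± 0.25 against 152 ± 17 CPM. CDK regulators were lower in 15 of 25 and higher in 2, E2F5 (0.68 ± 0.15, with 18.6% of its exonic bases shared with genes on the opposite strand) and CCND1 (0.31 ± 0.10, 566 ± 31 against 455 ± 13 CPM). RB1 fell by 0.35 ± 0.07 and CDKN1A by 0.38 ± 0.08, and CDKN1B stood at 20.5 ± 1.0 against 19.5 ± 2.4 CPM. FoxO genes were higher in 4 and lower in 2 of 26, 8 and 2 adjusted over the list alone (median 0.15), with MXD4 at 0.61 ± 0.06, CCNG2 at 0.57 ± 0.07 and INSR at −0.57 ± 0.11. Of ATF4 genes 4 were higher, SLC7A11 at 0.51 ± 0.11 among them, and PHGDH was lower at −0.49 ± 0.12. LPAR6, a receptor for lysophosphatidic acid, rose by 0.71 ± 0.15.

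At 15 h 340 genes were higher and 1387 lower, of which 6 and 420 by at least 2-fold, with a median log2 change of 0.266 among the higher and −0.544 among the lower. The E2F, G2/M and CDK regulator lists were called with both correlations (estimated: adjusted p = 9e-10, 9e-10 and 7.7e-05). The FoxO call (adjusted p = 0.0019) and the ATF4 call (0.039) were lost with an estimated correlation (adjusted p = 0.11 and adjusted p = 0.85). CCND1 lost its call without DMSO replicate 1 (0.33), 2 (0.30) or 3 (0.34) or palbociclib replicate 2 (0.28) or 3 (0.33), and PHGDH without DMSO replicate 2 (−0.40) or palbociclib replicate 2 (−0.40). The 340 higher genes became 145 without a filter, 611 with the library axis covariate, 164 without the 5 libraries, 211 with exon length trends removed, and 189, 208 and 207 without DMSO replicate 1, DMSO replicate 2 and palbociclib replicate 3.

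**Figure D2:**
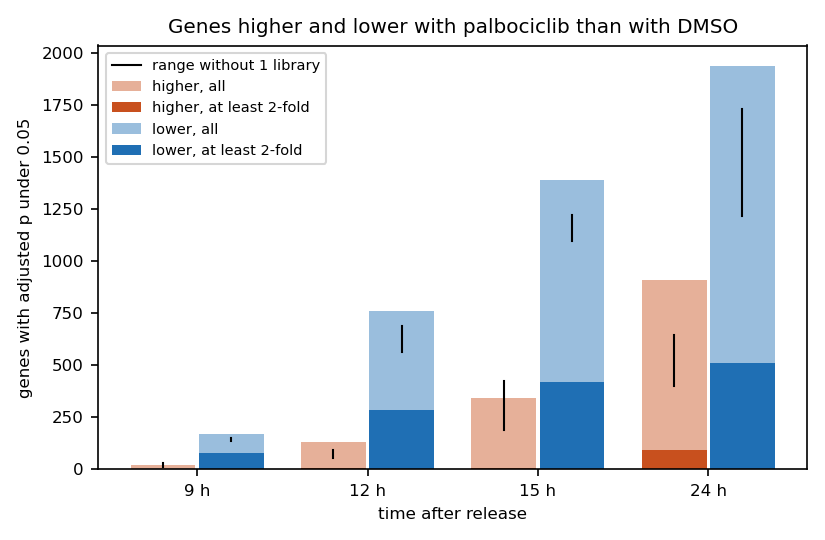
Number of genes called higher and lower with palbociclib than with DMSO at each time, at an adjusted p below 0.05 (light bars) and with at least a 2-fold change (dark bars), with black lines for the range of the light counts when 1 library was left out. Lower genes outnumbered higher genes at each time, 170 to 18 at 9 h and 1937 to 910 at 24 h.

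At 24 h the G2/M list had the lowest median of the 21 lists. All 50 G2/M genes were lower (median −4.79), with KIF20A, a mitotic kinesin gene, at 1.10 ± 0.19 against 180 ± 9.2 CPM (−7.37 ± 0.21; chromosome 5, 138178719 to 138187715), PLK1 at 1.70 ± 0.95 against 162 ± 6.2 (12.9% of its exonic bases are shared with genes on the opposite strand) and BIRC5, the gene of survivin, at 0.867 ± 0.42 against 100.4 ± 1.0. All 64 E2F G1/S genes were lower as well (median −2.31), with E2F1 at −2.52 ± 0.17 and CDC6 at −2.69 ± 0.14. CCNA2 stood at 2.90 ± 0.32 against 178 ± 6.3 CPM and CCNB1 at 23.6 ± 0.35 against 241 ± 16. CDK regulators were lower in 15 of 25 and higher in 2. CDKN1B fell by 0.93 ± 0.12, RB1 by 0.55 ± 0.09, CDKN1A by 0.44 ± 0.09 and CDKN2C by 3.20 ± 0.21, while CCND1 was higher by 0.41 ± 0.12. Cholesterol and fatty acid synthesis genes were higher in 6 of 27, 9 adjusted over the list alone (median 0.15), led by MSMO1 (0.43 ± 0.07). Basal markers were higher in 3 of 12 (ITGB4, KRT6A and LAMB3), 6 adjusted over the list alone (median 0.15). Among genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, the largest rises included WNT9A, a Wnt ligand gene (1.28 ± 0.13, 22.8 ± 1.9 against 9.37 ± 0.39 CPM; chromosome 1, 227918656 to 227947898), MYPN (1.30 ± 0.19) and FYB (1.27 ± 0.24), and MXD4 rose by 1.00 ± 0.07.

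At 24 h 910 genes were higher and 1937 lower, of which 90 and 508 by at least 2-fold. The 910 became 1376 with the library axis covariate taken from genes outside the E2F G1/S, G2/M and CDK regulator lists. The E2F, G2/M and CDK regulator lists were called with both correlations (estimated: adjusted p = 7.9e-08, 2e-09 and 2.1e-04), and the cholesterol (adjusted p = 0.0023) and basal calls (0.0048) were lost with an estimated correlation (adjusted p = 0.70 and adjusted p = 0.23). Calls were lost for CCND1 without DMSO replicate 1 (0.41) or 3 (0.38) or palbociclib replicate 3 (0.33), for CDKN1A without palbociclib replicate 1 (−0.34), for ITGB4 without palbociclib replicate 3 (0.23) or the 5 libraries (0.27), for KRT6A without DMSO replicate 1 (0.20) or 3 (0.27) or palbociclib replicate 3 (0.14), and for LAMB3 without any of the 4 libraries (0.14 to 0.19). The higher genes were 499 without DMSO replicate 1, 397 without DMSO replicate 3, and 285 without the 5 libraries. The lower genes were 1216 without palbociclib replicate 1 and 1137 without the 5 libraries, which left 1 library in each 24 h group.

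The remaining lists were not called by camera at 24 h, but fry, which does not compare a list with other genes, called p53 targets (adjusted p = 0.00147), ATF4 genes (0.00342), polyadenylated histones (0.00394) and mesenchymal markers (0.0327) lower. Among p53 targets 3 of 26 were higher and 6 lower (adjusted p = 0.26), with DDB2 at −0.81 ± 0.10 and TP53INP1 at 0.82 ± 0.19. ERK output genes were split at 3 of 18 higher and 5 lower (adjusted p = 0.86), with DUSP4 at 0.40 ± 0.08 and FOSL1 at −0.78 ± 0.09. The DUSP4 call was lost without the 5 libraries (0.35). Of ATF4 genes 7 of 21 were lower (adjusted p = 0.078), PHGDH, the first enzyme of serine synthesis, by −2.22 ± 0.15. FoxO genes had 5 of 26 higher and 1 lower (adjusted p = 0.26), polyadenylated histones 2 of 14 higher and 4 lower (0.15), ribosome biogenesis 3 of 40 lower (0.25), immediate early genes 2 of 22 lower (0.86), NF-κB cytokines 2 of 15 higher and 1 lower (0.13), mesenchymal markers 2 of 12 lower (0.52), YAP and TGF-β targets 1 of 16 higher and 2 lower (0.81), and lysosomal genes 1 of 20 higher and 2 lower (0.57). Interferon genes had 1 of 28 lower (0.57), and glycolysis, squamous and luminal lists each had 1 member higher (0.63, 0.57 and 0.57). The ERK output list had a median of 0.01 and a mean of −0.05 and the squamous list −0.01 and 0.04, and with library totals the squamous list, not called, changed sign.

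**Figure D3:**
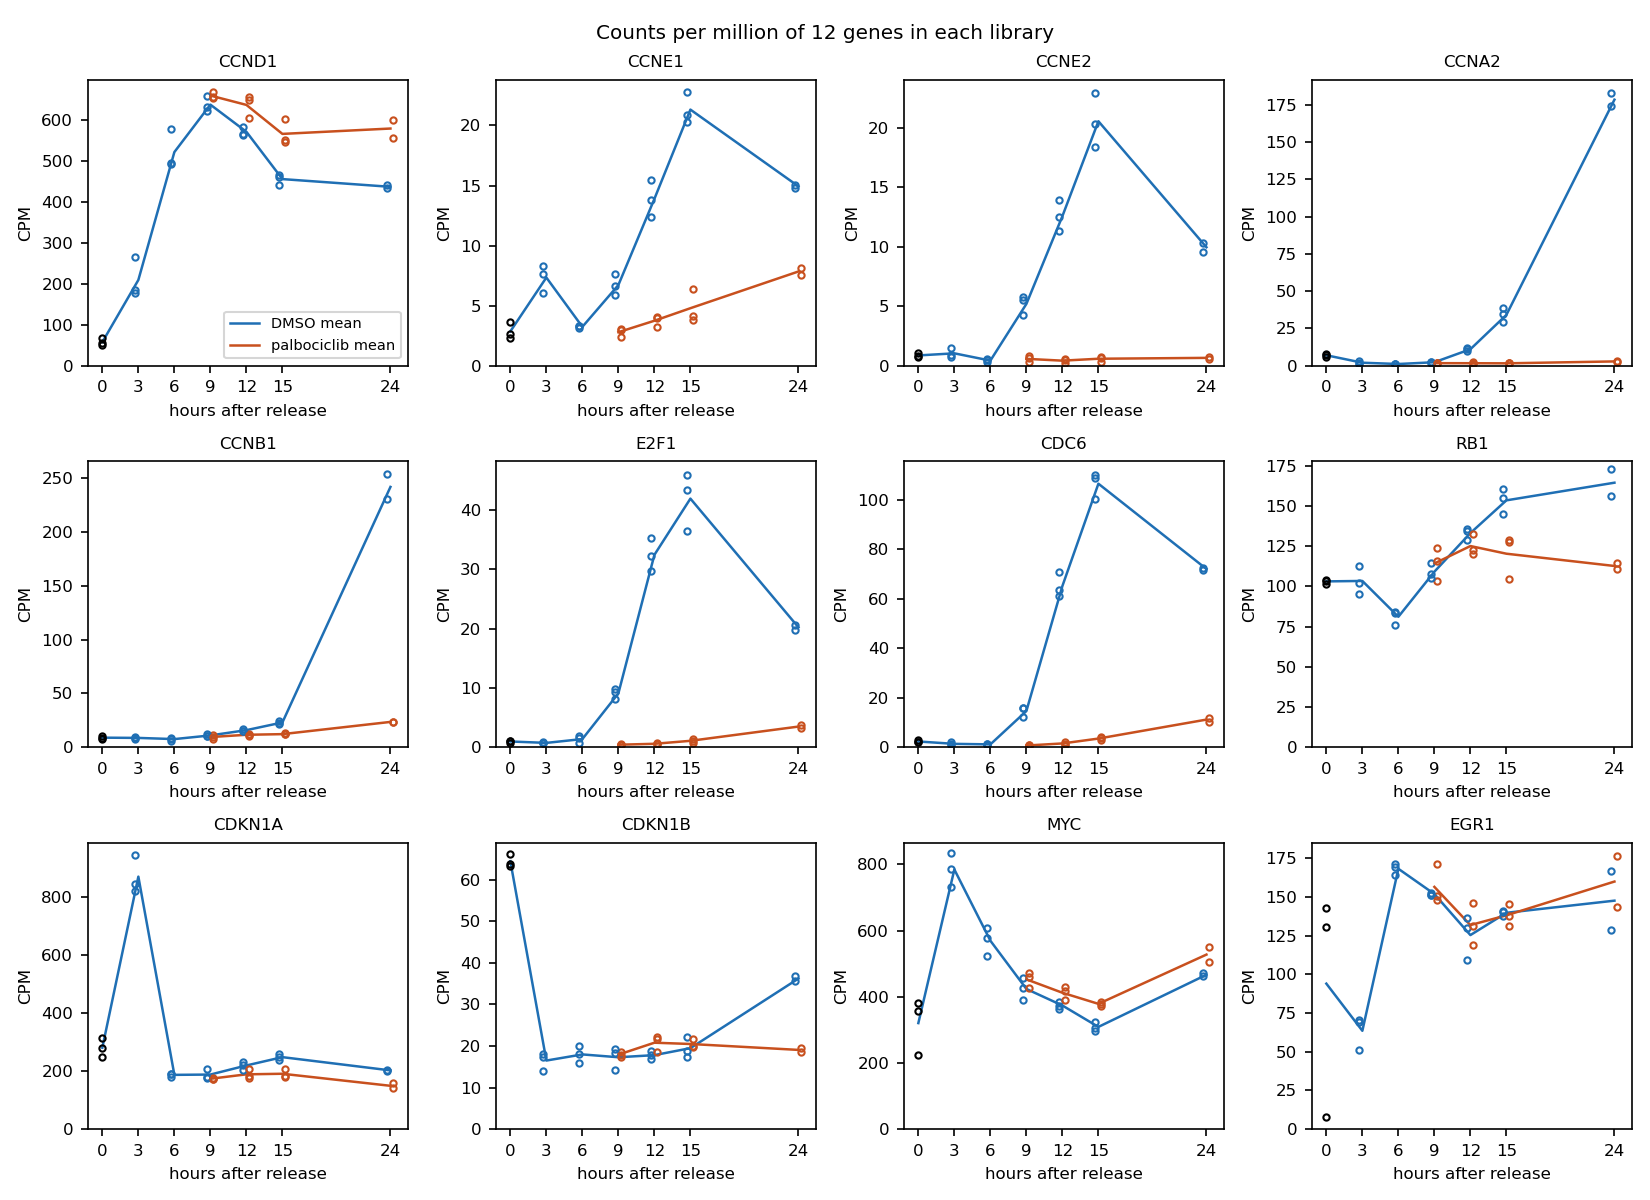
CPM of 12 named genes in each library (points, black for the starved cells at 0 h) on linear axes from 0 against hours after release, for DMSO (blue) and palbociclib (orange), with lines through the group means. CCND1 rose with both treatments, to 637 and 659 CPM at 9 h, while E2F1 stood at 9.10 CPM with DMSO and 0.452 with palbociclib at that time.

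The palbociclib effects at 9 and 15 h were compared in an interaction test. The effect on 61 of 64 E2F G1/S genes, 63 adjusted over the list alone, was more negative at 15 h (median −1.69), and so was that on 48 of 50 G2/M genes (median −3.15). MYBL2 changed by −5.97 ± 1.02, BIRC5 by −5.26 ± 0.63, MKI67 by −5.21 ± 0.43 and CCNA2 by −3.92 ± 0.33. E2F1 (−0.92 ± 0.40) and CDC6 (−0.65 ± 0.34) did not pass this test. CDK regulators were more negative in 11 of 25, 14 adjusted over the list alone with 2 more positive (median −0.26), and FoxO genes more positive in 1 of 26 (median 0.09). There were 21 more positive and 618 more negative genes, 4 and 282 by at least 2-fold. The 4 were TGM5 and, named after their values were seen, RCSD1, NID1 and a clone locus. Camera called the E2F (adjusted p = 1.8e-133), G2/M and CDK regulator (3.7e-10) lists lower and the FoxO list higher (0.02; adjusted p = 0.29 with an estimated correlation). The 21 genes became 33 with RLE factors, 34 with DESeq2, 46 without a filter, 50 with the library axis covariate and 10 without the 5 libraries.

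Between 15 and 24 h the effects on G1/S and G2/M genes moved apart. As a list, G2/M genes rose with palbociclib over these hours, but by less than with DMSO. The more negative effect on them was therefore not a further fall with the drug. The effect became less negative for 28 of 64 E2F G1/S genes and more negative for 3, 42 and 5 adjusted over the list alone (median 0.64), and became more negative for 30 of 50 G2/M genes, 35 adjusted over the list alone (median −1.41). FAM111B changed by 4.47 ± 0.48, E2F1 by 2.74 ± 0.28, CDC6 by 2.23 ± 0.20 and DTL by 2.14 ± 0.18, against KIF20A by −3.59 ± 0.46, PLK1 by −3.27 ± 0.38 and CCNB1 by −2.44 ± 0.15. CDKN1B changed by −0.998 ± 0.16. Cholesterol genes were more positive in 3 of 27 (median 0.17) and ATF4 genes more negative in 6 of 21 (median −0.25). In all 167 genes were more positive and 303 more negative, 43 and 87 by at least 2-fold. The E2F (adjusted p = 9e-23; 0.0011 with an estimated correlation) and G2/M (1.8e-52) calls held, while with an estimated correlation the cholesterol (3.7e-04), ATF4 (5.7e-07), basal (0.0096) and ribosome biogenesis (0.0049) calls were lost (adjusted p = 0.47, 0.12, 0.33 and 0.85). The 167 became 99 in a fit of the contrast's own libraries, 316 with the axis covariate, 108 with exon length trends removed and 44 without the 5 libraries, and was 92 and 84 without DMSO 15 h replicate 1 and palbociclib 15 h replicate 2, and 81, 62 and 67 without DMSO 24 h replicate 1, DMSO 24 h replicate 3 and palbociclib 24 h replicate 1. The 303 became 131 without the 5 libraries and 176 without palbociclib 24 h replicate 1.

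The released cells with palbociclib were also compared with the starved start. Palbociclib groups had 5505 higher and 6440 lower genes at 9 h, 5525 and 6380 at 12 h, 5536 and 6306 at 15 h, and 5409 and 5818 at 24 h. CCND1 stood at 659 ± 7.3 CPM at 9 h and 579 ± 31 at 24 h with palbociclib, against 57.7 ± 9.3 at 0 h, and CDKN1B at 17.9 ± 0.52 at 9 h against 64.5 ± 1.6. The E2F G1/S list was not called against 0 h at 9, 12 or 15 h (medians −0.11, −0.02 and 0.12), and at 24 h 39 of 64 members were higher and 11 lower (median 0.56, adjusted p = 0.0012; adjusted p = 0.23 with an estimated correlation). E2F1 rose to 3.51 ± 0.28 CPM at 24 h from 0.999 ± 0.22 at 0 h and CDC6 to 11.2 ± 1.1 from 2.39 ± 0.39. G2/M genes were lower than at 0 h at 9, 12 and 15 h (medians −1.70, −1.85 and −1.51; adjusted p = 0.11, 0.10 and 0.17 with an estimated correlation) and not called at 24 h (median −0.38). All 27 cholesterol genes were higher at 24 h (median 2.11, adjusted p = 0.036 with an estimated correlation).

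The overlap of release and drug effects was counted only between contrasts that share no library. Of 5699 genes higher with DMSO at 12 h than at 0 h and 1387 lower with palbociclib at 15 h, 844 were in both, where independent lists would share 501. The 844 were 14.8% of the genes raised on release. Of the 1387, 335 had fallen on release (549 for independent lists) and 208 were called neither way. Of 5911 genes higher with DMSO at 15 h and 759 lower with palbociclib at 12 h, 599 were in both, against 284 for independent lists. The 599 were 10.1% of the genes raised on release. Of the 759, 90 had fallen on release (298 for independent lists) and 70 were called neither way. With at least 2-fold in both, the overlaps were 238 and 252 against 65.6 and 47.6. As a level per library, the E2F G1/S list was lower with palbociclib by −1.36, −2.77, −3.28 and −2.59 at 9, 12, 15 and 24 h, and the G2/M list by −0.50, −2.06, −3.38 and −4.92. At 9, 12 and 15 h no palbociclib library overlapped a DMSO library in either list (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). Such separation was not particular to them. It also held for the CDK regulator and ATF4 lists at each of these times and for the FoxO list at 12 and 15 h. The p53 and ribosome biogenesis lists were separated at none of them.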

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

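The tests of RNA mixing, of a single library and of late-entering cells were chosen after the result was seen, whereas the interaction tests and the splits were planned. Each value here stands out because the palbociclib effect differed between times in an interaction test (edgeR, adjusted over 15787 genes or, for lists, camera over 21 lists). From 9 to 15 h the effect became more positive for 21 genes and more negative for 618. List medians changed by −1.69 for E2F G1/S, −3.15 for G2/M, −0.26 for CDK regulators and 0.089 for FoxO genes, whose call was lost with an estimated correlation (adjusted p = 0.295). Among named genes the changes were −0.84 for CCNE1, −2.07 for CCNE2 (37.1% of its exonic bases are shared with genes on the opposite strand), −3.92 for CCNA2, −0.67 for CCNB1, −0.41 for RB1 and −1.54 for MCM2. The rule for large changes added 1.10 for TGM5, 0.64 for ZNF283, 0.60 for SLC16A4 and 0.53 for KLF8, and −5.97 for MYBL2, −5.26 for BIRC5, −5.21 for MKI67 and −4.89 for FOXM1 (15.9% shared with a gene on the opposite strand). Calls were lost for CCNB1 without palbociclib 9 h replicate 1 (−0.54), for CCNE2 without palbociclib 9 h replicate 2 (−1.68), and for RB1 without DMSO 9 h replicate 1 (−0.39), DMSO 15 h replicate 3 (−0.37), palbociclib 9 h replicate 2 (−0.34) or palbociclib 15 h replicate 1 (−0.31). CCNE1 kept its call in the fits without DMSO 9 h replicate 2, DMSO 15 h replicate 1 or 3, palbociclib 9 h replicate 2 or palbociclib 15 h replicate 2, and lost it without each other library (−0.82 to −0.69). TGM5 kept its call without DMSO 9 h replicate 2 or 3, DMSO 15 h replicate 1 or palbociclib 15 h replicate 3 and lost it otherwise (0.89 to 1.14), and SLC16A4 kept its call without DMSO 9 h replicate 1, DMSO 15 h replicate 2 or 3 or palbociclib 15 h replicate 1 and lost it otherwise (0.48 to 0.64). In refits of the 12 libraries at these times, 584 genes were called, 8 of 50 splits called as many and the highest other split called 923. Of those 8 splits 7, the real one included, kept the 15 h labels in place and so carried the 15 h drug effect by construction, so these splits do not decide whether chance can be excluded. The highest split that moved the 15 h labels called 597.

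From 15 to 24 h the effect became more positive for 167 genes and more negative for 303. List medians changed by 0.64 for E2F G1/S, −1.41 for G2/M, 0.17 for cholesterol, −0.25 for ATF4, 0.13 for basal and −0.12 for ribosome biogenesis genes. With an estimated correlation the calls of the last 4 lists were lost (adjusted p = 0.473, 0.123, 0.328 and 0.851). As a list, G2/M genes rose with palbociclib over these hours, but by less than with DMSO, so the more negative effect was not a further fall. Among named genes the effect changed by 1.197 for CCNE1, −1.57 for CCNA2, −2.44 for CCNB1, −0.998 for CDKN1B, 2.74 for E2F1, 1.09 for MCM2 and 2.23 for CDC6. The rule for large changes added 4.47 for FAM111B and 2.14 for DTL, and −3.59 for KIF20A, −3.27 for PLK1 (12.9% shared with genes on the opposite strand), −3.16 for PSRC1 and −2.87 for NEURL1B. Without replicate 3 of DMSO 24 h and of the palbociclib groups the CCNE1 and CCNA2 calls were lost (1.08 and −1.55). The 167 genes were 92, 84, 81, 67 and 62 without DMSO 15 h replicate 1, palbociclib 15 h replicate 2, DMSO 24 h replicate 1, palbociclib 24 h replicate 1 and DMSO 24 h replicate 3, and the 303 were 176 without palbociclib 24 h replicate 1.

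With palbociclib, E2F G1/S genes were higher at 24 h than at 15 h. RNA from cells like those with DMSO at 24 h would bring G1/S and G2/M transcripts in equal shares, but the E2F G1/S share was at least 2.81 times the G2/M share (5.54% and 5.67% against 1.97% and 1.45% in the 2 libraries). Against a single outlying library, the lower 24 h library lay 0.676 above the highest 15 h library in mean log2 CPM. Cells that entered the cycle late may account for the rise: against DMSO 15 h the ratio of the shares was 0.488, and against DMSO 12 h 0.213, as a stage between 15 and 24 h would give. A partial rise within all cells could give the same ratios, so these cannot be told apart in bulk RNA.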

How the results depend on the processing

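The library axis covariate, removal of GC or exon length trends, the same 3 taken from all genes outside the E2F G1/S, G2/M and CDK regulator lists, leaving out 5 libraries (replicate 3 of DMSO 24 h and of each palbociclib group) and TMM factors without the cell cycle lists were tests chosen after seeing the data, and the other settings were planned. Of the values that answer comparisons, 510 kept their direction and side of the threshold, or stayed within 1.5 times, under a setting and 118 moved. The 118 also hold small shifts in list level that kept their direction and stayed within 1.5 times. An example is E2F G1/S at 24 h, from −2.593 to −2.579 with TMM factors without the cell cycle lists. Of the other results, 25173 kept them, 775 were no longer past the threshold, 181 newly passed it and 104 moved. No called result changed direction under the settings run. Depth limits low genes, and counting intervals cover counting error only. Where a 24 h library is left out, the lone sample is assumed to vary like the other groups. The cause was not tested for the changes below.

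Genes higher with palbociclib than with DMSO at 9, 12 and 15 h (18, 131 and 340) became 36, 266 and 611 with the axis covariate and 11, 75 and 211 with exon length trends removed, and the 131 at 12 h became 85 with GC trends removed. Taken from the genes outside the cell cycle lists, the axis covariate gave 259, 594 and 1376 higher genes at 12, 15 and 24 h and 48 and 325 more positive genes from 9 to 15 h and from 15 to 24 h, the GC trend 532 at 15 h and 45 from 9 to 15 h, and the exon length trend 33 from 9 to 15 h. Without a filter there were 59 at 12 h, 145 at 15 h and 275 lower genes at 9 h (170). A fit of the contrast's own libraries gave 11 at 9 h and 239 at 12 h. Without the 5 libraries, higher genes were 6, 57, 164 and 285 at 9, 12, 15 and 24 h (910 at 24 h), and lower genes 1137 at 24 h (1937). For the change from 9 to 15 h, 21 genes more positive became 33 with RLE factors, 34 with DESeq2, 46 without a filter, 50 with the axis covariate and 10 without the 5 libraries. For that from 15 to 24 h, 167 became 108 with exon length trends removed, 316 with the axis covariate, 99 in a fit of its own libraries and 44 without the 5 libraries, and 303 more negative became 131 without them. Leaving out 1 library gave 9 to 29 higher genes at 9 h, 54 to 91 at 12 h, 189 to 423 at 15 h and 397 to 646 at 24 h, 1216 to 1727 lower genes at 24 h, and from 15 to 24 h 62 to 189 more positive and 176 to 350 more negative genes.

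With replicate number as a block, higher genes were 62 at 9 h and 240 at 12 h, 32 genes were more positive from 9 to 15 h, and 2 lists in place of 1 were higher at 9 h. The numbers were not taken to pair the libraries: over 146 same-numbered pairs the median correlation of deviations was 0.0469 (−0.398 to 0.496, 57 over 0.1), against −0.0363 over 290 differently numbered pairs, and 18 of 31 libraries correlated best with their own number. In DMSO at 3 to 15 h against 0 h the correlations were 0.271 to 0.419 for replicate 2 and 0.178 to 0.364 for replicate 3, but 0.0146 to 0.0609 for replicate 1. Deviations within a group cancel out, so where replicates 2 and 3 lie opposite, little is left for replicate 1. Its low correlations therefore do not decide against pairing in these groups.

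With an estimated correlation, lists called higher fell from 1, 2, 2 and 2 to 0 in palbociclib against DMSO at 9, 12, 15 and 24 h, from 7, 4, 4, 7 and 7 to 2, 1, 1, 2 and 3 in DMSO at 3, 6, 9, 12 and 15 h against 0 h, from 3, 4, 4 and 5 to 1, 1, 1 and 2 in palbociclib at 9, 12, 15 and 24 h against 0 h, from 1 to 0 from 9 to 15 h and from 3 to 1 from 15 to 24 h. Lists called lower fell from 2, 6, 6, 5, 5 and 4 to 1, 3, 1, 1, 1 and 1 in DMSO at 3 to 24 h, from 6, 6, 6 and 4 to 1, 1, 1 and 2 in palbociclib against 0 h, and from 3 to 1 from 15 to 24 h. Fry, which does not compare a list with other genes, called 0 lists higher at 9 h and 1 at 15 h, 7 lower at 24 h, and 0 more positive from 9 to 15 h. Against 0 h fry called 12, 10, 11, 13, 13 and 11 lists higher in DMSO at 3 to 24 h and 11, 11, 12 and 11 in palbociclib at 9 to 24 h, and 8, 10 and 8 lower in DMSO at 3, 6 and 24 h and 8 in palbociclib at 24 h.

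The overlaps of 844 and 599 genes became 238 and 252 with at least 2-fold in both. With a prior count of 0.5 the differences in list level became −2.87, −3.36 and −2.62 for E2F G1/S at 12, 15 and 24 h and −0.56, −2.27, −3.62 and −5.02 for G2/M at 9, 12, 15 and 24 h. The E2F G1/S difference at 24 h, −2.59, was −2.56 with library totals, −2.58 with TMM factors without the cell cycle lists, and −2.60 to −2.58 with 1 replicate number left out.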

Other observations

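Of the tests in this part, those on 5 further gene lists and 3 further contrasts, and those of scaling, the library axis, GC content, exon length and cycling cells, were chosen after the result was seen, whereas the splits were planned. Genes of recombination and the Fanconi anaemia pathway were lower with palbociclib in 18, 23, 24 and 24 of 24 members at 9, 12, 15 and 24 h (medians −1.03, −2.28, −3.17 and −2.79; 5 of the 24 are also in the E2F G1/S list), with BRCA2 at −3.88 ± 0.14 (SE) and BLM at −3.91 ± 0.14 at 15 h. Genes that maintain chromatin and DNA methylation were lower in 13, 21, 23 and 23 of 24 (medians −0.37, −1.05, −1.56 and −1.81; 7 of the 24 are also in the E2F G1/S list), with LMNB1, the gene of lamin B1, at −3.42 ± 0.08 at 15 h and HMGB2 at −4.36 ± 0.14 at 24 h. Nucleoporin genes were lower in 13, 17 and 22 of 26 at 12, 15 and 24 h (medians −0.19, −0.29 and −0.49), with NUP210 at −2.67 ± 0.21 at 24 h. With an estimated correlation the camera calls of these lists held at 24 h (adjusted p = 2.98e-08, 1.04e-07 and 2.05e-04), and the nucleoporin call at 9 h (median −0.07, adjusted p = 0.0068) was lost (adjusted p = 0.40). Camera p-values of the further lists were adjusted over the 21 planned and the 5 further lists together. SR proteins and CLK kinases had 2 of 19 members higher at 9 h (median 0.04, adjusted p = 0.020; adjusted p = 0.47 with an estimated correlation) and 8 lower at 24 h (adjusted p = 0.058). The 2 were SRSF5 and SRSF6, whose rises at 9 h were known when the list was chosen, so the 9 h result is not separate from theirs. Aminoacyl-tRNA synthetases had small positive medians at 9, 12 and 15 h (0.06, 0.09 and 0.08) that were lost with an estimated correlation (adjusted p = 0.50, 0.63 and 0.72).

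Cells held with palbociclib for 15 h were compared with DMSO cells at 6 h, a contrast in which both drug and time since release differ. Here 4023 genes were higher and 4288 lower, 686 and 992 by at least 2-fold. Cholesterol and fatty acid synthesis genes were higher in 24 of 27 (median 1.37, adjusted p = 9.1e-18; adjusted p = 0.054 with an estimated correlation), with SCD at 2.18 ± 0.08. Ribosome biogenesis genes were lower in 32 of 40 and higher in 1 (median −0.37; adjusted p = 0.42 with an estimated correlation). At the shared time of 15 h, palbociclib minus DMSO in list level was −0.013 for cholesterol and 0.027 for ribosome biogenesis genes (exact two-sided permutation p = 0.8 and 0.5). The differences of these lists from DMSO at 6 h therefore do not show a drug effect. From 15 to 24 h with palbociclib, 1761 genes rose and 1469 fell. E2F G1/S genes rose in 39 of 64 and fell in 1 (median 0.61; adjusted p = 0.004 with an estimated correlation), G2/M genes rose in 35 of 50 (median 1.22; 1.8e-04) and cholesterol genes in 25 of 27 (median 0.87; 0.0012). With DMSO over the same hours, all 50 G2/M genes rose (median 2.485), while E2F G1/S genes rose in 13 and fell in 22 of 64 and the list was not called (adjusted p = 0.67).

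The genes higher with palbociclib at 15 and 24 h had medians of 0.266 and 0.427 (lower quartiles 0.213 and 0.314), and against scaling after the loss of cell cycle transcripts, the counts given up by genes called lower raised the share of all other genes by at most 0.039 and 0.094 log2 over pairs of libraries. With the axis covariate 99.4% (97.9 to 99.9, 95% binomial interval) and 99.3% (98.6 to 99.8) stayed called, and 99.4% and 98.6% with one from genes not chosen by the drug tests. At 15 h these covariates moved folds by a median of only 0.0024 and 0.0031 log2 over all genes. Calls could hardly end there, so the 15 h shares do not test the axis. At 24 h the medians were 0.0202 and 0.0355, small beside the fold of 0.427 and an SE of 0.107 in the genes called higher. The covariates as fitted thus held little of these folds, but so small a shift does not decide whether the axis was a cause. Across genes the drug effect at 24 h went with the loading on the axis at a Spearman rho of −0.192, genes not being independent. In a fit without replicate 3 of DMSO 24 h and of the palbociclib groups 40.3% and 25.7% stayed called, but the others had medians of 0.240 before and 0.222 after (SE 0.071 and 0.083) and of 0.382 and 0.341 (SE 0.105 and 0.157), so calls ended more through the larger SE than through smaller folds, and a batch or RNA quality difference, not named in the labels, was not excluded for part of them. With trends over GC content or exon length removed, the median gene kept at least 97.0% and 99.6% of its fold at 15 h. At 24 h it kept at least 92.6% and 92.5%, with trends from either set of genes. Over all genes these removals moved folds by medians of only 0.0027 to 0.0202 log2 at 15 h and 0.0067 to 0.0357 at 24 h. The fitted trends thus held little of these folds, but so small a removal does not decide whether GC content or length was a cause. Genes called higher had a median GC content of 45.6% and 55.1% against 50.3% in control genes, chosen for little drug difference. Their median exon length was 5574 and 5352 nt against 3909 nt. With GC trends removed 72.9% (67.9 to 77.6) and 81.8% (79.1 to 84.2) stayed called and with exon length trends removed 59.4% (54.0 to 64.7) and 68.6% (65.4 to 71.6), where lost genes went at 15 h from 0.211 to 0.196 (SE 0.066 to 0.074) and from 0.215 to 0.214 (0.066 to 0.080) and at 24 h from 0.260 to 0.233 (0.088 to 0.094) and from 0.295 to 0.259 (0.093 to 0.106), so lost calls do not show a trend as their cause, and a response of the cells to the drug stays open, untested.

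G2/M transcripts were higher in the starved cells than 6 h after release. Against scaling, the median log2 change of G2/M genes lay below that of all genes (difference −1.758). A share of cycling cells in the starved culture may contribute: measured against DMSO 24 h RNA, the E2F G1/S share at 0 h was 0.483 times the G2/M share (1.08% to 1.12% against 2.12% to 2.55%). Slow decay of G2/M transcripts in arrested cells was not tested.

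For each contrast of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. In refits of the 6 libraries, palbociclib against DMSO called 152 genes at 9 h, where 2 of 10 splits called as many and the highest other called 192, 1019 at 12 h (highest other 0) and 1515 at 15 h (highest other 2). Palbociclib at 15 h against DMSO at 6 h called 7600, DMSO at 3, 6, 9, 12 and 15 h against 0 h 8757, 10968, 11292, 11537 and 11542, and palbociclib at 9, 12 and 15 h against 0 h 11360, 11333 and 11057, each with 1 of 10 splits as large and 0 genes in the highest other split. The split at 9 h with 192 genes set palbociclib replicate 1 with DMSO replicates 1 and 3 against the other libraries. Their scores as the library axis covariate were −0.117, 0.331 and −0.609, below those of the other libraries (0.824 to 1.243). This split thus went with the axis, and it called more genes than the drug labels did.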
